A study of Mus musculus with 18 samples.

How the data were processed

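The series holds 18 bulk poly(A) RNA libraries from mouse bone marrow cultures of 4 days, in 6 groups of 3. BALB/c marrow, WT or labelled Cysltr1-deficient, received GM-CSF, GM-CSF and IL-6, or GM-CSF and EMT6 conditioned medium. Each sample pooled marrow of 3 mice, per the labels. The genotype contrast is called the KO effect in some names of comparisons, and IL-6 and EMT6 medium effects are always against GM-CSF alone in the same genotype unless another control is named.

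The deposited values used are raw counts per feature, 1 file per sample, that the authors made with HISAT2 2.1.0 and HTSeq 0.13.5 on build mm10, per the submitters' processing notes. DESeq2 1.34.0, also named in those notes, was not used to make the counts. The notes give no annotation, strand setting or filter, and the library kit named in the labels is not stated to be directional. Reads of overlapping genes on opposite strands are therefore uncertain, and so are counts within families of near-identical genes. The 55536 gene IDs of the files all occur in GENCODE M21, which gave a symbol for 55450 of them, while 86 had none. The files also hold 26248 numbered entries, which took 0.0399% to 0.446% of feature counts, 97 spike-in entries with 0 counts, and the 5 summary lines of HTSeq. All of these stayed out of library sizes and tests. Reads in no annotated feature averaged 14.2%, 14.5% and 36.2% of the total in WT GM-CSF, IL-6 and EMT6 medium libraries and 17.6%, 19.5% and 50.2% in labelled-deficient ones, and reads not aligned averaged 7.09%, 6.86% and 10.7%, then 7.38%, 7.82% and 13.3%. A deposited table of normalized values is each library's count divided by 1 factor and was not used here.

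Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3 on all 18 libraries with 1 mean per group, and p-values were adjusted by Benjamini and Hochberg within each comparison. Genes with an adjusted p under 0.05 are called. The filter kept 28334 genes, and the common biological coefficient of variation was 0.0480. The 11 comparisons are IL-6 and EMT6 medium in each genotype, EMT6 medium against IL-6 in WT, the genotype in each culture and averaged, and the interactions of genotype with IL-6 and with EMT6 medium. Counts were also simulated from gene means over all 18 libraries, with changes planted in the WT IL-6 group (25544 genes tested). Dispersion followed the trend with abundance, without spread between genes of like abundance, so the setting is more even than the data. For IL-6 in WT the test recovered 8 of 50 genes changed 1.2-fold, 23 of 50 changed 1.5-fold, 40 of 50 changed 2-fold and 46 of 50 changed 4-fold, with 5 false calls. Gene counts ran from 9.58 to 32.0 M per library, so small changes of low-abundance genes are missed, more so in EMT6 medium libraries.

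The comparisons, the 28 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. A total of 27 lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with p-values adjusted over the lists of a comparison; the list of sex-linked genes had only Xist measured. A list member rose or fell when it was called among all genes, and where the count differs after adjusting p over the members of the list only, it is given as adjusted over the list alone. The named genes are the 8 largest rises and 8 largest falls for IL-6 and EMT6 medium in WT and for the genotype in each culture and averaged, and 4 each elsewhere. These had an adjusted p under 0.05 and a mean CPM of at least 5 in the higher group, had no predicted-gene name and, outside the interactions, showed no overlap between replicates. The rule adds the 4 members of each list with the smallest p and 32 genes fixed beforehand, such as Cysltr1, Alox5, Socs3, Arg1 and Nos2. Some genes that the rule names are not reported here. For a gene with at most 3 counts in all libraries of a group, the ratio of summed CPM with its exact binomial interval replaces the fitted change.

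Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, a filter at mean CPM of 5 in at least 1 group, an absolute log2 fold change of at least 1, only the groups compared, a replicate block, each library left out, and for lists an estimated correlation and fry. Those added after seeing the data subtract a background (each gene's exon length times the library's density of reads in no annotated feature) or leave out the EMT6 medium libraries. Scaling shifts of fold changes over 0.1 log2 are given here. With library sizes alone in place of TMM the median shift was 0.50 for EMT6 medium in WT, 0.62 in labelled-deficient marrow, 0.50 against IL-6, 0.12, 0.15 and 0.24 for the genotype under GM-CSF, IL-6 and EMT6 medium, 0.17 averaged and 0.12 for the interaction with EMT6 medium. With DESeq2 size factors it was -0.14 for EMT6 medium in WT, -0.27 in labelled-deficient marrow, -0.15 against IL-6, -0.10 for the genotype under EMT6 medium and -0.13 for its interaction. Without the low-count filter it was -0.28, -0.14 and -0.23 for EMT6 medium in labelled-deficient marrow, the genotype under EMT6 medium and the interaction. With the filter at mean CPM of 5 it was 0.27, 0.32 and 0.29, and with background subtraction 0.27, 0.32 and 0.25, for EMT6 medium in WT, in labelled-deficient marrow and against IL-6, and 0.11 for the genotype under EMT6 medium with subtraction. Location used Fisher's exact test over tested genes. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.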

Results

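Gene expression was measured by bulk poly(A) RNA sequencing of mouse bone marrow cells cultured for 4 days, an in vitro setting for myelopoiesis, the formation of granulocytes, monocytes and their relatives. The marrow came from BALB/c wild-type (WT) mice and from mice described as deficient in Cysltr1, the type 1 receptor for cysteinyl leukotrienes. All cultures received GM-CSF (40 ng/mL), a growth factor for granulocytes and macrophages. It was given alone, with IL-6 (40 ng/mL), a cytokine that signals through STAT3, or with 50% (v/v) conditioned medium. That medium had been on EMT6 cells, a mouse mammary carcinoma line, for 24 h. The 6 groups held 3 samples each, and every sample was a pool of marrow from 3 mice. The comparisons ask how IL-6 and tumour medium shift the cultures, and how the Cysltr1 genotype alters the cultures and those shifts.

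Libraries held 9.58 to 32.0 M counts in annotated genes. Of 55536 gene IDs 28334 had enough counts to be tested. The depth was not even across groups. It averaged 25.2 M in WT GM-CSF, 26.7 M in WT IL-6 and 15.9 M in WT EMT6 medium libraries, and 23.1, 23.3 and 10.9 M in the same cultures of labelled-deficient marrow. EMT6 medium libraries also differed in composition. Reads in no annotated feature made up 36.2% ± 1.39 (SD, n = 3) in WT and 50.2% ± 0.152 in labelled-deficient EMT6 medium libraries, against group means of 14.2% to 19.5% elsewhere. A set of 1420 olfactory and vomeronasal receptor genes, which myeloid cells are not known to use as a family, took 0.0844% ± 0.00781 and 0.186% ± 0.00682 of gene counts in the EMT6 medium libraries and 0.0169% to 0.0293% in the other groups. Of the 13262 genes called higher with EMT6 medium in WT, 10216 lay under 1 CPM in WT GM-CSF cultures. Replicates within a group differed by more than counting noise in each pair (chi-square per degree of freedom 1.58 to 6.35), so none copies another and all 18 were kept.

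**Figure D1:**
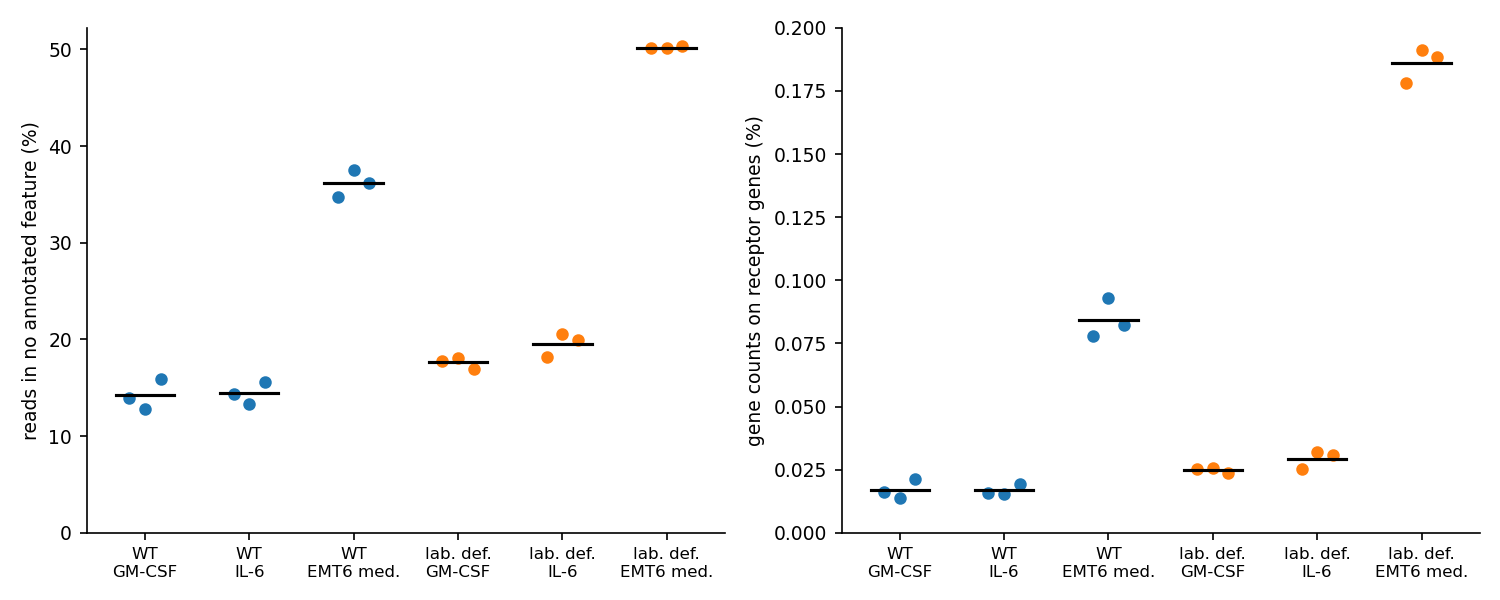
Percent of reads in no annotated feature (left) and percent of gene counts on 1420 olfactory and vomeronasal receptor genes (right) in each of the 18 libraries, by group (lab. def., labelled deficient); points are libraries and bars are group means. Both measures are highest in the EMT6 medium libraries, with means of 50.2% and 0.186% in the labelled-deficient group.

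Cysltr1 itself (X chromosome, mm10 106574346 to 106603679, minus strand) was counted in all 18 libraries, and its transcript was not lower in the libraries labelled deficient. Under GM-CSF its counts were 1259, 915 and 1718 in the WT libraries and 1697, 1904 and 1271 in the labelled-deficient ones. With IL-6 they were 1872, 1575 and 1981 against 1969, 1867 and 1994, and with EMT6 medium 83, 68 and 79 against 113, 122 and 96. The averaged log2 fold change was 0.44 ± 0.05 (adjusted p = 2.68e-10). By culture it was 0.35 under GM-CSF, 0.15 under IL-6 and 0.82 under EMT6 medium. In EMT6 medium libraries Cysltr1 averaged 4.85 CPM by library size in WT and 10.3 in labelled-deficient marrow. Reads outside annotated features would give 1.86 and 3.94 CPM there, so the background holds a part of those values. Counts of a whole gene cannot show an internal deletion or an inserted cassette, so they do not check the allele, and the text writes labelled deficient throughout. Fndc3c1, at 106420041 to 106485401 on the same chromosome, separated the labels, as the rule that names genes requires. Its counts were 8 to 19 in WT and 588 to 1018 in labelled-deficient GM-CSF libraries, 4 to 13 against 936 to 1044 with IL-6, and 34 to 42 against 54 to 77 with EMT6 medium. In EMT6 medium libraries its means by library size were 2.36 CPM in WT and 5.96 CPM in labelled-deficient marrow. They lie near the 2.28 and 4.83 CPM expected from reads outside annotated features. After background subtraction the genotypes still differed there (log2 fold change 2.72, adjusted p = 0.0032). The separation is thus not background alone by that estimate, though its size is uncertain. The estimate may also be too high. In WT EMT6 medium libraries it rests on 5.69 counts per kb, against 2.50 on receptor genes. In WT GM-CSF and IL-6 libraries Fndc3c1 was not above the background estimated in this way (0.51 and 0.34 CPM against 0.58 and 0.57 expected). The size of its fold changes between genotypes therefore depends on that background. Xist, expressed from an inactive X chromosome, had 6999 to 28311 counts and the Y-linked Ddx3y had 0 to 3 in each library, so both genotypes show the same female pattern.

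**Figure D2:**
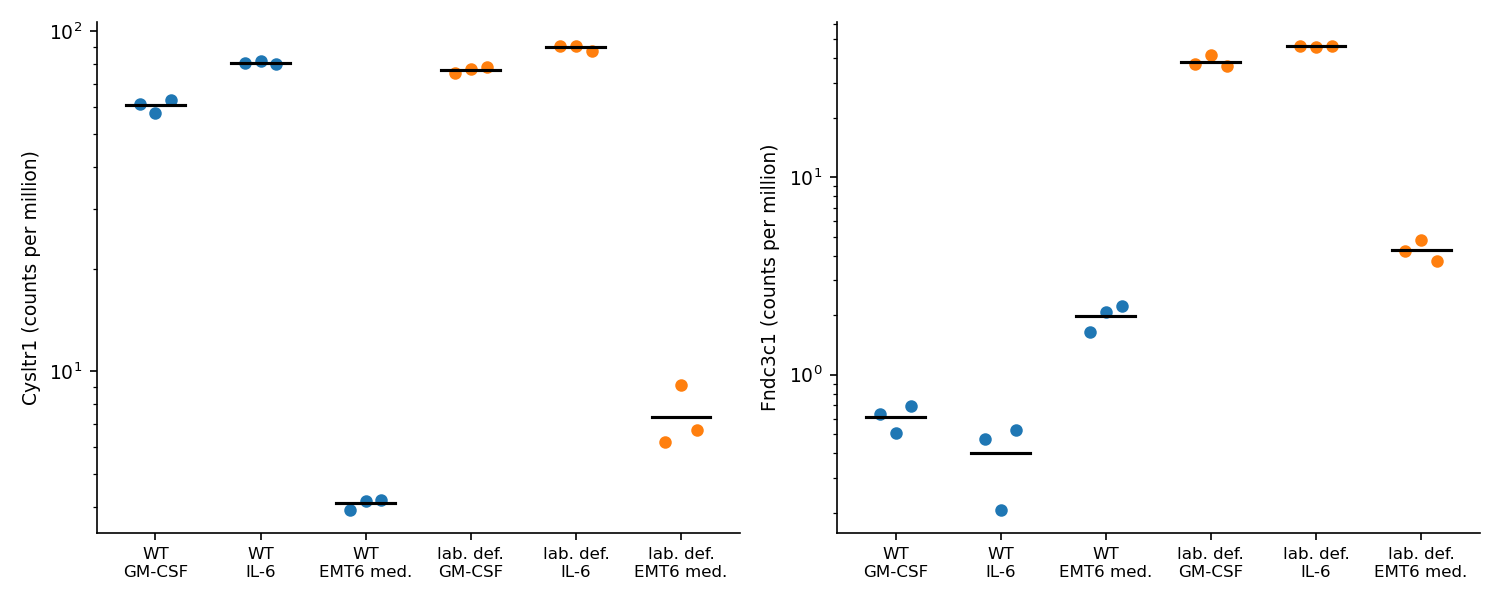
Counts per M of Cysltr1 and Fndc3c1 in each library on a log axis; points are libraries and bars are group means. Cysltr1 averages 60.5 in WT and 77.1 in labelled-deficient GM-CSF libraries, whereas Fndc3c1 averages 0.61 and 38.5 there. In EMT6 medium libraries Fndc3c1 lies near the background estimated from reads outside annotated features.

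The first comparison asks what IL-6 added to GM-CSF in WT marrow. Values after a gene name are log2 fold changes ± a standard error derived from the F statistic, with 3 samples per group. Adjusted p-values rest on a spread between replicates that was estimated over all 6 groups together. Whether the replicates of a group came from separate pools of mice is not stated, so the spread between mice may not be covered. Ccl8, a monocyte-attracting chemokine, rose most (4.58 ± 0.09), followed by the acute-phase gene Saa3 (2.71 ± 0.09), the cholesterol ester-forming enzyme Soat2 (2.65 ± 0.08), the stress pseudokinase Trib3 (2.65 ± 0.06), and Bex1 (2.63 ± 0.19). The collagenase Mmp13 (2.58 ± 0.05), the magnesium channel Trpm6 (2.45 ± 0.14) and Adm, which encodes adrenomedullin (2.21 ± 0.07), came next. Among the largest falls were the chemokine Ccl17 (-2.59 ± 0.07), the kallikreins Klk1b9 (-2.55 ± 0.07), Klk1b27 (-2.49 ± 0.10) and Klk1b1 (-2.17 ± 0.08) and the eosinophil-type ribonucleases Ear2 (-2.17 ± 0.11) and Rnase2a (-2.11 ± 0.07). The heat shock gene Hspa1a also fell (-2.11 ± 0.10). Kallikrein, ribonuclease and Hspa1 genes have near-identical copies, and their counts are uncertain between copies. In all, 6135 genes passed the test, 2940 higher and 3195 lower, and 574 of them changed at least 2-fold (249 higher). Higher genes were 47.9% of the calls, and 56.6% without the low-count filter.

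IL-6 responsive genes moved. Of 22 measured IL-6 and STAT3 targets, 12 rose and 2 fell (median 0.23, adjusted p = 2.09e-07; 12 up and 3 down adjusted over the list alone). The feedback inhibitor Socs3 (0.91 ± 0.05), Timp1 (1.26 ± 0.08), Bcl3 (0.84 ± 0.06) and the receptor subunit Il6st (0.79 ± 0.05) were among the rises. Suppressive mediators of myeloid cells rose in 11 of 18 cases and fell in 1 (median 0.34, adjusted p = 1.06e-14). Nos2 (1.64 ± 0.06), the arginine transporter Slc7a2 (1.06 ± 0.06), Havcr2 (1.03 ± 0.07), Cd274, which encodes PD-L1 (0.61 ± 0.05), and arginase Arg1 (0.85 ± 0.07) were higher. Glycolysis and hypoxia genes rose in 16 of 20 cases (median 0.28, adjusted p = 1.04e-23; 18 up and 0 down adjusted over the list alone), led by Adm and Ero1l (0.77 ± 0.04). ATF4 and amino acid stress genes rose in 18 of 19 cases and fell in 1 (median 0.81, adjusted p = 1.49e-34), with Atf5 (1.42 ± 0.05), Aldh1l2 (1.77 ± 0.08) and Chac1 (1.97 ± 0.09) after Trib3.

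Other groups fell. All 19 measured cholesterol synthesis genes were lower (median -1.08, adjusted p = 1.71e-45), including Cyp51 (-1.59 ± 0.05), Hmgcs1 (-1.37 ± 0.05), Fdft1 (-1.43 ± 0.06) and Msmo1 (-1.10 ± 0.05). Cell cycle genes fell in 22 of 23 cases (median -0.83, adjusted p = 8.06e-40), for example the mitotic kinase gene Cdk1 (-1.14 ± 0.06) and Mcm7 (-1.02 ± 0.06). Each of the 10 primary granule genes fell (median -0.60, adjusted p = 9.72e-20), with neutrophil elastase Elane (-1.23 ± 0.05) and Prtn3 (-1.22 ± 0.06). Of the secondary and tertiary granule genes, 13 of 15 fell (median -0.37, adjusted p = 2.31e-12). Ngp (-1.40 ± 0.05) and Camp (-1.35 ± 0.06) fell and Mmp8 rose (0.90 ± 0.05). Of 19 mature neutrophil genes 10 fell and 5 rose (median -0.21, adjusted p = 0.00648, and adjusted p = 0.280 with an estimated correlation; 6 up and 10 down adjusted over the list alone). Ly6g (-1.19 ± 0.05) and S100a8 (-0.96 ± 0.07) were lower and Csf3r (0.83 ± 0.06) higher. MHC class II presentation genes fell in 11 of 12 cases (median -0.72, adjusted p = 1.04e-22), including H2-Aa (-1.16 ± 0.05) and Cd74 (-0.86 ± 0.04). Dendritic cell genes fell in 10 of 17 (median -0.29, adjusted p = 4.24e-05), including Cd209a (-1.87 ± 0.08). The alternative activation genes Retnla (-1.34 ± 0.06) and Ccl24 (-0.92 ± 0.07) were lower and Tgm2 (0.64 ± 0.05) higher in a list with 2 up and 7 down (median -0.55, adjusted p = 2.43e-05; 3 up and 7 down adjusted over the list alone).

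Conditioned medium from EMT6 cells changed more genes in WT cultures than IL-6 did. The neutrophil growth factor gene Csf3 (9.61 ± 0.14) and the neutrophil chemoattractant Cxcl1 (8.55 ± 0.09) rose most. The antiviral genes Ifit3 (7.31 ± 0.23), Rsad2 (7.02 ± 0.09) and Rtp4 (6.16 ± 0.11), the chemoattractant Cxcl2 (6.26 ± 0.07) and the pantetheinase Vnn3 (6.22 ± 0.09) rose too. Il1f6, an IL-1 family cytokine, had 539 counts in EMT6 medium and 2 in GM-CSF libraries, a ratio of 429 with a 95% exact binomial interval of 118 to 3548 for counting error. The largest falls were in Klk1b9 (-8.33 ± 0.15), Klk1b11 (-7.36 ± 0.10), Rnase2a (-7.36 ± 0.11), the lectins Cd209c (-7.28 ± 0.26) and Asgr2 (-7.07 ± 0.09), Retnla (-7.10 ± 0.09), Ccl17 (-6.98 ± 0.13) and Sectm1a (-6.58 ± 0.22). The test called 23045 genes, 13262 higher and 9783 lower, 15319 of them at least 2-fold (11209 higher). With a filter at mean CPM of 5 it called 12611 genes, and 45.0% of calls were higher in place of 57.5%. After background subtraction 8426 genes were higher and 8825 lower.

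Interferon-stimulated genes rose in 19 of 23 cases and fell in 2 (median 3.67, adjusted p = 1.83e-09), with Ifit2 (5.15 ± 0.09), Oas3 (3.46 ± 0.07) and the regulator Irf7 (3.45 ± 0.06) beside Rsad2. Of 23 inflammatory cytokines and NF-kB targets, 17 rose and 5 fell (median 2.01, adjusted p = 4.89e-06, and adjusted p = 0.0905 with an estimated correlation), including Ccl3 (4.50 ± 0.06) and Tnf (2.01 ± 0.07). The prostaglandin enzymes Ptgs2 (5.97 ± 0.08) and Ptges (5.24 ± 0.08) rose while Ptgs1 (-2.47 ± 0.05) and the thromboxane synthase Tbxas1 (-3.52 ± 0.07) fell. The prostanoid list with 6 up and 8 down did not pass (median -0.20, adjusted p = 0.792), with 5 up and 4 down under the filter at mean CPM of 5 and 6 and 5 after background subtraction. Cd274 (2.18 ± 0.05), Hmox1 (3.13 ± 0.05), Nos2 (1.44 ± 0.06), Il10 (3.13 ± 0.23) and Il1b (1.76 ± 0.06) were higher, and Arg1 (-3.58 ± 0.08) and Slc7a2 (-2.67 ± 0.06) lower. The suppressive list that holds several of these rose in 5 and fell in 11 cases (median -1.0, adjusted p = 0.0730).

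Falls were common among expressed genes. Of 11175 genes with a mean CPM of at least 5, 8167 were called lower and 1839 higher. Above about 5 CPM the median log2 fold change was -0.59, against 0.49 over all tested genes. The list test sets each list against all tested genes, so a list of expressed genes can come out lower without being particular. GM-CSF and STAT5 targets fell in 14 of 16 cases (median -2.26, adjusted p = 2.05e-09), among them Il2ra (-4.14 ± 0.06), Ccl22 (-4.20 ± 0.07) and Socs2 (-2.96 ± 0.06). Both receptor subunits Csf2ra (-2.30 ± 0.05) and Csf2rb (-1.33 ± 0.05) were lower. The leukotriene list fell in 10 of 15 cases and rose in 3 (median -1.0, adjusted p = 0.000133). The 5-lipoxygenase Alox5 (-2.46 ± 0.05), its activating protein Alox5ap (-1.57 ± 0.05), the leukotriene B4 receptor Ltb4r1 (-2.63 ± 0.05) and Cysltr1 (-3.89 ± 0.09) fell. MHC class II genes fell in 11 of 12 cases (median -2.75, adjusted p = 8.21e-10), for example H2-DMb2 (-4.14 ± 0.06). Primary granule genes fell in 10 of 10 (median -2.16, adjusted p = 9.27e-09), for example myeloperoxidase Mpo (-4.49 ± 0.06). Secondary and tertiary granule genes fell in 13 and rose in 2 of 15 cases (median -1.57, adjusted p = 4.55e-08), including Ltf (-4.96 ± 0.06). Each of the 23 cell cycle genes was lower (median -1.05, adjusted p = 4.94e-11), as were 18 of 19 cholesterol synthesis genes (median -1.10, adjusted p = 2.61e-09). Top2a was among the lower cell cycle genes (-1.68 ± 0.05). Alternative activation genes fell in 10 of 12 cases (median -3.01, adjusted p = 1.45e-06), such as Mgl2 (-5.09 ± 0.08) and Chil3 (-5.21 ± 0.09). Lymphoid genes, present at low levels in these cultures, rose in 11 of 16 cases (median 1.07, adjusted p = 0.00553, and adjusted p = 0.0700 with an estimated correlation), with Cd79b (1.68 ± 0.06) and Ighm (1.30 ± 0.05). They did so in the libraries in which receptor genes took a larger share of counts.

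Set directly against IL-6, EMT6 medium again showed Csf3 (9.01 ± 0.13), Cxcl1 (7.91 ± 0.09), Rsad2 (7.00 ± 0.09) and Ifit3 (6.61 ± 0.21) higher, and fibronectin Fn1 (-6.33 ± 0.14), the purinergic receptor P2ry13 (-6.16 ± 0.13), Klk1b9 (-5.78 ± 0.21) and Retnla (-5.76 ± 0.09) lower in WT marrow. Interferon-stimulated genes were higher in 21 of 23 cases (median 3.44, adjusted p = 2.07e-10). ATF4 and amino acid stress genes were lower in 16 of 19 (median -1.66, adjusted p = 8.34e-07, and adjusted p = 0.0582 with an estimated correlation), including Trib3 (-3.19 ± 0.06). Glycolysis and hypoxia genes were lower in 18 of 20 (median -1.14, adjusted p = 2.07e-10), including Pdk1 (-2.50 ± 0.05). Among suppressive mediators, Arg1 (-4.43 ± 0.08) was lower and Cd274 (1.57 ± 0.05) higher with EMT6 medium. Macrophage genes were lower in 14 and higher in 4 of 19 cases (median -1.06, adjusted p = 0.000228, and adjusted p = 0.113 with an estimated correlation), led by the mannose receptor Mrc1 (-4.88 ± 0.08). The test called 23191 genes, 13623 higher and 9568 lower; with the filter at mean CPM of 5, 47.1% of 12556 calls were higher in place of 58.7%. After background subtraction 8791 genes were higher. Above about 5 CPM the median log2 fold change was -0.59, against 0.53 over all tested genes, so falls of lists of expressed genes need not be particular.

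In labelled-deficient marrow IL-6 raised Ccl8 (3.84 ± 0.07), Mmp13 (2.61 ± 0.05), Bex1 (2.39 ± 0.19) and Aebp1 (2.32 ± 0.20) most. Klk1b9 (-2.47 ± 0.08), Klk1b27 (-2.30 ± 0.13), Ear2 (-2.28 ± 0.12) and Cd209a (-2.21 ± 0.11) fell most. Secondary and tertiary granule genes fell in 13 of 15 cases (median -0.84, adjusted p = 1.53e-26), with Ltf (-1.70 ± 0.05) and Camp (-2.07 ± 0.08). MHC class II genes fell in 11 of 12 (median -0.56, adjusted p = 1.62e-24), cell cycle genes in 20 of 23 (median -0.49, adjusted p = 5.74e-23; 0 up and 21 down adjusted over the list alone). Cholesterol synthesis genes fell in 16 of 19 (median -0.35, adjusted p = 8.68e-18; 0 up and 17 down adjusted over the list alone). Glycolysis and hypoxia genes rose in 17 of 20 cases (median 0.24, adjusted p = 1.15e-26; 18 up and 1 down adjusted over the list alone), with Adm (1.97 ± 0.07) and Bnip3 (0.63 ± 0.05). STAT3 targets rose in 9 and fell in 3 of 22 cases (median 0.11, adjusted p = 0.00144, and adjusted p = 0.116 with an estimated correlation; 10 up and 4 down adjusted over the list alone), with Socs3 at 0.51 ± 0.05. The ATF4 and amino acid stress list, higher in nearly all members in WT, had 7 up and 7 down here (median 0.02, adjusted p = 0.934; 7 up and 8 down adjusted over the list alone), for example Ddit4 (0.74 ± 0.05) up and Shmt2 (-0.53 ± 0.05) down. The test called 4057 genes, 1571 higher and 2486 lower (332 at least 2-fold, of which 207 were higher and 125 lower). Higher genes were 38.7% of all calls with TMM scaling, 28% with DESeq2 size factors in edgeR and 26.6% with DESeq2. With only the groups compared in the fit, 2390 genes were higher.

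EMT6 medium in labelled-deficient marrow raised Cxcl1 (7.22 ± 0.09), Rsad2 (6.43 ± 0.09) and Vnn3 (6.28 ± 0.10) and lowered Rnase2a (-6.88 ± 0.11), Ccl17 (-6.74 ± 0.12), Asgr2 (-6.37 ± 0.09) and Chil3 (-6.09 ± 0.09). Csf3 had 1146 counts against 3 in GM-CSF libraries, a ratio of 806 with a 95% exact binomial interval of 275 to 3913 for counting error. Interferon-stimulated genes rose in 19 of 23 cases (median 3.02, adjusted p = 5.28e-06). Of 23 inflammatory genes 16 rose while 7 fell (median 2.09, adjusted p = 0.0246, and adjusted p = 0.362 with an estimated correlation). GM-CSF and STAT5 targets fell in 14 of 16 cases (median -2.45, adjusted p = 2.28e-09), and MHC class II genes in 11 of 12 (median -2.36, adjusted p = 1.26e-08). ATF4 and amino acid stress genes fell in 16 of 19 cases (median -2.14, adjusted p = 3.43e-07, and adjusted p = 0.0544 with an estimated correlation), with Slc7a5 (-4.01 ± 0.08) and Atf5 (-3.07 ± 0.06). Cholesterol synthesis genes rose in 11 cases and fell in 6 of 19, without passing the list test (median 0.36, adjusted p = 0.232), with Insig1 (2.07 ± 0.06) and Hmgcs1 (1.25 ± 0.05) higher. Cell cycle genes had 14 falls and 7 rises (median -0.21, adjusted p = 0.258), a balance of 8 and 8 after background subtraction and of 10 rises and 5 falls with the filter at mean CPM of 5. The heat shock genes Hspa1b (4.41 ± 0.06) and Hspa1a (4.39 ± 0.07) rose. The test called 24700 genes, 15383 higher and 9317 lower. Of these calls 62.3% were higher, against 49.0% of 12914 with that filter and 50.7% of 18718 after background subtraction. Of 11175 genes with a mean CPM of at least 5, 7872 were called lower and 2153 higher. Falls of lists of expressed genes thus need not be particular here either.

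The next comparisons set labelled-deficient against WT marrow within each culture. Under GM-CSF alone, Fndc3c1 (5.93 ± 0.13), the retinol carrier Rbp4 (4.52 ± 0.11), carbonic anhydrase Car6 (3.20 ± 0.19), and Btbd11 (2.94 ± 0.12) were higher by most. Trib3 (2.88 ± 0.06), the glycine transporter Slc6a9 (2.78 ± 0.14), the cell cycle inhibitor Cdkn2a (2.71 ± 0.11) and the phospholipase Pla2g5 (2.69 ± 0.17) were higher. H2-Q7 (-3.87 ± 0.17), Arhgap19 (-3.84 ± 0.08), Elane (-3.17 ± 0.05) and Prtn3 (-2.70 ± 0.07) were among the genes lower by most. Retnlg (-2.65 ± 0.06), the farnesyl diphosphate synthase Fdps (-2.63 ± 0.12) and Nkg7 (-2.62 ± 0.14) were lower too. H2-Q genes differ between mouse strains and have close copies, so reads can be split among them. The test called 7735 genes, 2858 higher and 4877 lower (1210 at least 2-fold, 590 of them higher); 36.9% of calls were higher, and 52.2% without the low-count filter.

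Neutrophil genes were lower together. Of the 19 mature neutrophil genes 17 fell and 1 rose (median -0.83, adjusted p = 1.59e-21), with Ly6g (-1.77 ± 0.05) and S100a8 (-1.31 ± 0.07). Primary granule genes fell in 9 of 10 cases (median -1.65, adjusted p = 5.51e-18), and secondary and tertiary ones in 14 of 15 (median -1.05, adjusted p = 8.12e-23). NADPH oxidase genes fell in 6 of 7 (median -0.36, adjusted p = 4.34e-09), led by Cybb (-1.40 ± 0.05). Monocyte genes fell in 10 of 15 (median -0.61, adjusted p = 3.58e-07), with F13a1 (-1.50 ± 0.06) and Ly6c2 (-1.64 ± 0.08). All 19 cholesterol synthesis genes were lower (median -1.29, adjusted p = 4.17e-40), including Hmgcs1 (-1.61 ± 0.05) and Fdft1 (-1.94 ± 0.06). Of the cell cycle genes 22 of 23 were lower (median -1.40, adjusted p = 6.48e-39), including Ccnb2 (-1.88 ± 0.06). ATF4 and amino acid stress genes were higher in 17 of 19 cases (median 1.05, adjusted p = 2.98e-32), with Asns (1.65 ± 0.06) and Chac1 (2.47 ± 0.09). This comparison and the IL-6 effect in WT share the 3 WT GM-CSF libraries, so their changes in cholesterol synthesis and ATF4 genes are not independent. Among 23 inflammatory genes 13 were higher and 5 lower (median 0.31, adjusted p = 4.93e-05, and adjusted p = 0.0952 with an estimated correlation). Il6 (2.54 ± 0.09) and Cxcl3 (1.51 ± 0.05) were up and Tnf (-0.87 ± 0.07) down. Leukotriene genes fell in 7 and rose in 2 of 15 cases (median 0.01, adjusted p = 0.0247 with the test pointing lower, and adjusted p = 0.0952 with an estimated correlation). Lta4h (-1.52 ± 0.05), Alox5 (-0.69 ± 0.05) and Alox5ap (-0.66 ± 0.05) were lower. Eosinophil genes fell in 7 of 10 cases (median -1.55, adjusted p = 2.81e-09), including Epx (-1.99 ± 0.06). All 12 MHC class II genes fell (median -0.70, adjusted p = 2.20e-19).

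With IL-6 present, the labelled-deficient cultures again had higher Fndc3c1 (6.77 ± 0.14), Rbp4 (5.39 ± 0.09), Car6 (2.48 ± 0.16), Btbd11 (2.47 ± 0.11), Cdkn2a (2.28 ± 0.10) and Pla2g5 (2.17 ± 0.16), with the transcriptional repressor Zhx2 (2.16 ± 0.11) and the ubiquitin ligase Mid1 (1.95 ± 0.12). H2-Q7 (-3.83 ± 0.15), Retnlg (-3.56 ± 0.08), Arhgap19 (-3.16 ± 0.08), the deubiquitinase Otud3 (-3.14 ± 0.15), Camp (-2.85 ± 0.08), Elane (-2.66 ± 0.06), Mfap1a (-2.41 ± 0.10) and the ficolin Fcnb (-2.23 ± 0.13) were lower. Mfap1a has a close paralog, so its count is uncertain. Mature neutrophil genes fell in 16 of 19 cases (median -0.80, adjusted p = 2.50e-23; 1 up and 17 down adjusted over the list alone), and secondary and tertiary granule genes in 14 of 15 (median -1.51, adjusted p = 9.25e-29). Monocyte genes fell in 12 of 15 (median -0.61, adjusted p = 8.07e-14) and NADPH oxidase genes in 6 of 7 (median -0.32, adjusted p = 3.82e-08). The 19 cholesterol synthesis genes were again all lower (median -0.72, adjusted p = 7.43e-22), for example Mvd (-0.90 ± 0.05), and 22 of 23 cell cycle genes were lower (median -0.99, adjusted p = 4.17e-28). Suppressive mediators fell in 12 and rose in 4 of 18 cases (median -0.37, adjusted p = 8.79e-06, and adjusted p = 0.0883 with an estimated correlation; 4 up and 13 down adjusted over the list alone), including Nos2 (-0.99 ± 0.06). Glycolysis and hypoxia genes fell in 18 of 20 (median -0.39, adjusted p = 1.50e-21). Of the ATF4 and amino acid stress genes 13 rose and 2 fell (median 0.21, adjusted p = 3.91e-06, and adjusted p = 0.0592 with an estimated correlation; 14 up and 3 down adjusted over the list alone), with Psat1 (0.53 ± 0.05). The test called 8635 genes, 3420 higher and 5215 lower (1559 at least 2-fold, of which 1167 were higher and 392 lower). Higher genes were 39.6% of all calls, and DESeq2 called 2434 higher and 5424 lower.

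In EMT6 medium the genes that differed most were partly others. Mid1 (2.42 ± 0.11), the collagens Col6a2 (2.04 ± 0.28) and Col6a1 (1.73 ± 0.25), the heat shock genes Hspa1a (1.92 ± 0.06) and Hspa1b (1.83 ± 0.05), and fibrinogen Fgb (1.80 ± 0.22) were higher in the labelled-deficient cultures. So were the dynein Dnah8 (1.78 ± 0.07) and Sspnos (1.68 ± 0.22). Col6a2, Col6a1 and Sspnos averaged 5.05, 5.04 and 5.08 CPM in the higher group, just above the naming limit of 5. A gene with 3 kb of exon would get a background of 2.30 CPM by library size in those libraries. In WT EMT6 medium libraries it would get 1.08 CPM, so these rises are uncertain. H2-Q7 (-3.76 ± 0.11), the selenium carrier Selenop (-2.37 ± 0.07), Cbx2 (-2.10 ± 0.08), Csf3 (-2.04 ± 0.07), Mfap1a (-1.96 ± 0.12), Ptges (-1.94 ± 0.06) and Fabp3 (-1.77 ± 0.17) were lower. Of 27 lists 16 were called, each of them lower, and 16 with 2 of them higher after background subtraction. Of 11175 genes with a mean CPM of at least 5, 5159 were called lower and 1715 higher. Above about 5 CPM the median log2 fold change was -0.15, against 0.27 over all tested genes. A fall of a list of expressed genes thus need not be particular. Interferon-stimulated genes were lower in 16 of 23 cases (median -0.31, adjusted p = 2.94e-10, or 1 up and 18 down adjusted over the list alone), with Ifit2 (-1.47 ± 0.07) and Rsad2 (-0.91 ± 0.05). Inflammatory genes were lower in 14 and higher in 3 of 23 (median -0.30, adjusted p = 4.53e-11), with Ccl4 (-1.28 ± 0.05) and Tnf (-1.17 ± 0.06). Suppressive mediators fell in 14 of 18 cases and rose in 0 (median -0.41, adjusted p = 1.30e-10), including Arg2 (-0.94 ± 0.05), Nos2 (-0.75 ± 0.06) and Cd274 (-0.42 ± 0.05). Mature neutrophil genes fell in 16 of 19 cases (median -0.67, adjusted p = 2.35e-16), led by the lectin Clec4e (-1.43 ± 0.05). All 7 NADPH oxidase genes fell (median -0.47, adjusted p = 2.94e-10). Cell cycle genes fell in 16 of 23 cases (median -0.27, adjusted p = 6.51e-06). Cholesterol synthesis genes did not follow the other cultures, with 8 higher and 2 lower (median 0.13, adjusted p = 0.201), or 4 higher and 5 lower without the low-count filter. Hmgcs1 was among the higher (0.66 ± 0.05). Stromal and epithelial genes were higher in 9 and lower in 5 of 15 cases (median 0.70, adjusted p = 0.470), with Col3a1 (1.46 ± 0.17), in the libraries with the largest share of reads outside annotated features. The test called 14749 genes, 9143 higher and 5606 lower (3936 at least 2-fold, 3631 of them higher), and 9461 with the filter at mean CPM of 5. Higher genes made up 62.0% of the calls, 51.0% with DESeq2 size factors, 45.2% with DESeq2, 45.6% without the low-count filter and 39.9% after background subtraction. With 1 library left out the share was 45.9% to 59.9%, and without replicate 1 of WT EMT6 medium 5431 genes were higher and 6395 lower.

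Averaged over the 3 cultures, Fndc3c1 (4.60 ± 0.10), Rbp4 (3.62 ± 0.11), Btbd11 (2.19 ± 0.09), Mid1 (2.11 ± 0.06), Cdkn2a (1.94 ± 0.08), Zhx2 (1.92 ± 0.06) and the alarmin Il33 (1.51 ± 0.10) were highest in labelled-deficient marrow, each without overlap between genotypes in any culture. H2-Q7 (-3.82 ± 0.08), Arhgap19 (-2.68 ± 0.05), Otud3 (-2.48 ± 0.09), Elane (-2.25 ± 0.03), Mfap1a (-2.18 ± 0.06), the matrilin Matn4 (-2.18 ± 0.10), the eosinophil granule gene Prg3 (-1.89 ± 0.08) and Selenop (-1.88 ± 0.04) were lowest. Neutrophil and oxidase genes were lower, with 18 of 19 mature neutrophil genes (median -0.80, adjusted p = 1.22e-22) and all 7 NADPH oxidase genes (median -0.51, adjusted p = 1.31e-10). All 19 cholesterol synthesis genes (median -0.62, adjusted p = 7.28e-22) and 22 of 23 cell cycle genes (median -0.85, adjusted p = 9.05e-26) were lower, and 16 of 19 ATF4 and amino acid stress genes were higher (median 0.41, adjusted p = 3.34e-11). Of 27 lists 16 were called, 1 of them higher. Above about 5 CPM the median log2 fold change was -0.12, against 0.15 over all tested genes. The test called 15264 genes, 8308 higher and 6956 lower (1395 at least 2-fold, 1182 of them higher); 54.4% were higher, 46.0% to 54.9% with 1 library left out, 48.8% with DESeq2 size factors, 46.9% with DESeq2 and 43.4% after background subtraction. With the filter at mean CPM of 5, 5269 genes were higher. Without the EMT6 medium libraries, an alternative chosen after seeing the data, the mean of the other 2 cultures called 11021 genes, 4993 higher and 6028 lower. A knockout allele can carry flanking DNA of its strain of origin, so the location of these genes was tested. Mid1, H2-Q7, Matn4 and Dnah8 each lie within 1 Mb of another of 37 genes that changed at least 2-fold the same way in all 3 cultures, which limits reading them as effects of the receptor. Fndc3c1, also among the 37, lies 89 kb from Cysltr1, where such flanking DNA would lie, so the same limit holds for it. A gene without a neighbour in the set can differ through DNA of another strain too. Zhx2, Arhgap19, Otud3 and Mfap1a, which are such genes of the 37, are therefore not cleared of this limit. The genotype contrast as a whole cannot separate the receptor from such DNA. After background subtraction, an alternative chosen after seeing the data, 33 of the 37 stayed at least 2-fold the same way in all 3 cultures, and Btbd11 did not under EMT6 medium. The X chromosome held 510 of the 15264 called genes and 1012 of the 28334 tested (odds ratio 0.865, Fisher's exact test p = 0.0246), and after background subtraction the odds ratio was 0.872 (p = 0.0692). Within 10 Mb of Cysltr1, 94 of 165 tested genes were called (odds ratio 1.13, Fisher's exact test p = 0.435). Among calls of at least 2-fold, added after seeing the data, the X chromosome held 71 of 1395 (odds ratio 1.48, Fisher's exact test p = 0.00297) and the 10 Mb window 17 (odds ratio 2.23, p = 0.00351). Of those 17, 16 were higher, and all but Fndc3c1 lay under a mean CPM of 5 in every group. The excess in the window thus rests on low-abundance genes.

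**Figure D3:**
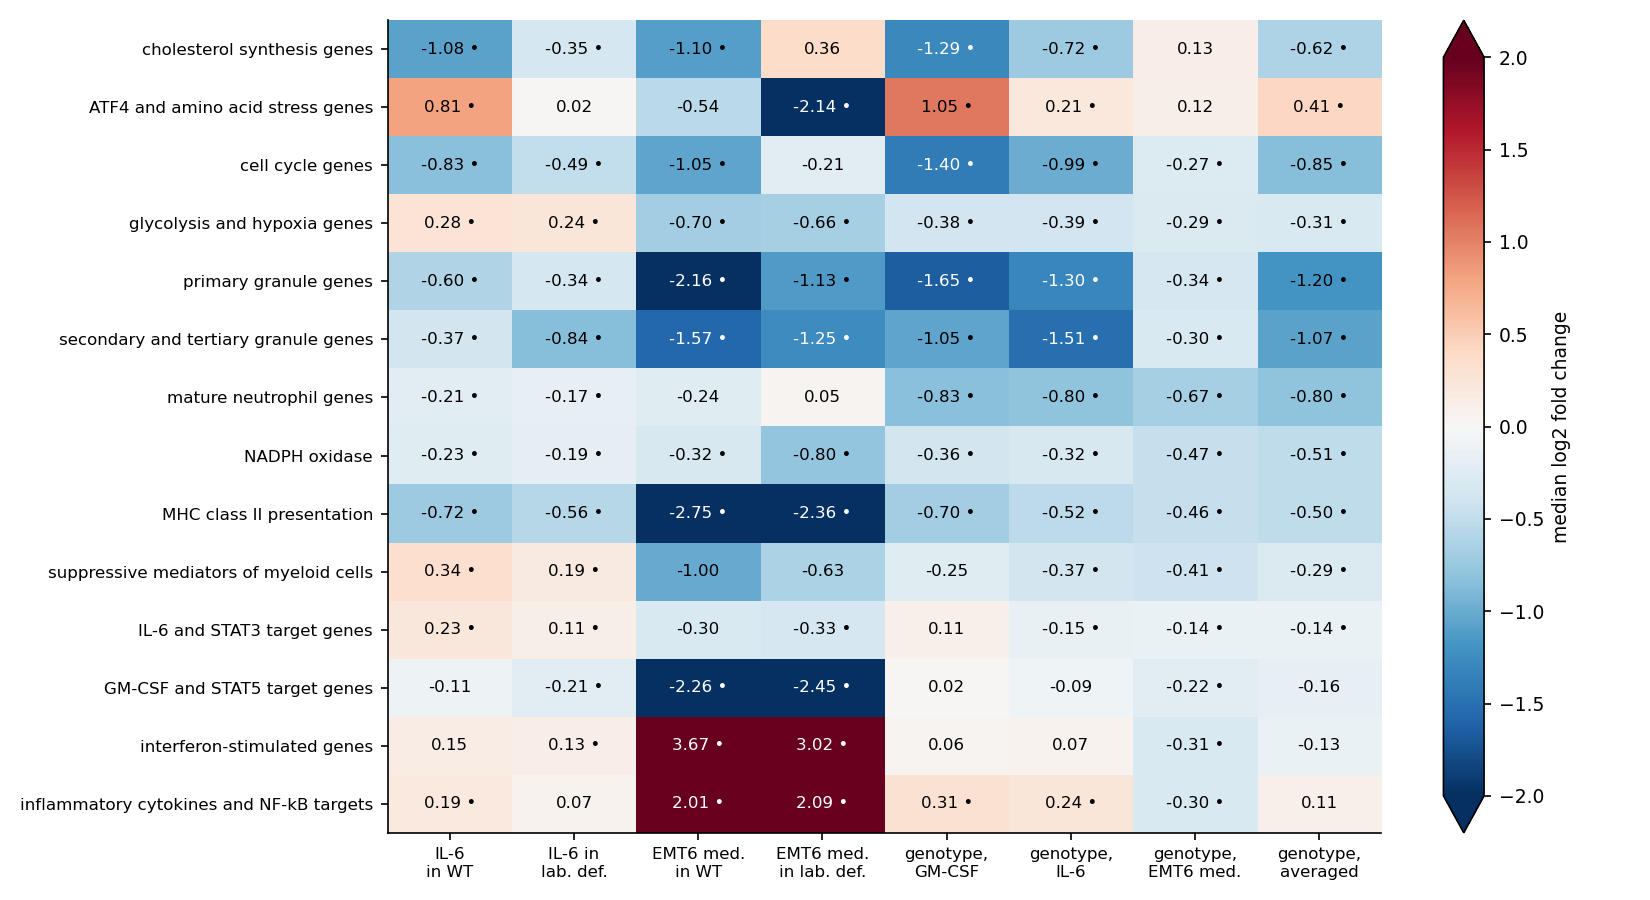
Median log2 fold change of 14 gene lists in 8 comparisons, as colour and printed value; a dot marks lists that pass camera at an adjusted p of 0.05. Cholesterol synthesis medians are -1.08 and -1.10 for IL-6 and EMT6 medium in WT and -1.29 for the genotype under GM-CSF.

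The interaction of genotype and IL-6 asks whether IL-6 changed labelled-deficient cultures by another amount than WT cultures. Relative to WT, the change was more positive for Dynlt1c (1.81 ± 0.45) and the complement genes C1qb (1.75 ± 0.16) and C1qa (1.65 ± 0.15), and more negative for Soat2 (-2.47 ± 0.10), Trib3 (-2.44 ± 0.08), Slc6a9 (-2.27 ± 0.19) and the amino acid transporter Slc1a4 (-2.26 ± 0.12). ATF4 and amino acid stress genes differed in 16 of 19 cases, each more negative (median -0.83, adjusted p = 1.11e-56). Cholesterol synthesis genes differed in 18 of 19, each more positive (median 0.67, adjusted p = 1.15e-36; 19 up and 0 down adjusted over the list alone). Cell cycle genes were more positive in 16 of 23 cases (median 0.34, adjusted p = 3.34e-17; 21 up and 0 down adjusted over the list alone), and secondary and tertiary granule genes more negative in 12 of 15 (median -0.34, adjusted p = 1.49e-18). STAT3 targets were more negative in 9 and more positive in 2 of 22 cases (median -0.15, adjusted p = 4.12e-06; 2 up and 10 down adjusted over the list alone), with Timp1 (-1.02 ± 0.11) and Socs3 (-0.39 ± 0.06). The interaction was called for 2091 genes, 828 more positive and 1263 more negative. The more positive share was 39.6% with TMM scaling, 24.7% with DESeq2 size factors, 22.1% with DESeq2, 25.4% without the low-count filter and 51.1% with the filter at mean CPM of 5. Of 185 genes at least 2-fold apart 120 were more positive. Without the EMT6 medium libraries 1283 genes were more positive and 1492 more negative.

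For EMT6 medium the interaction was more positive for Fdps (3.16 ± 0.20), the receptor gene Lilra5 (2.99 ± 0.38), Retnlg (2.96 ± 0.20) and Rtn1 (2.90 ± 0.21) and more negative for Fndc3c1 (-4.83 ± 0.26), Rbp4 (-3.58 ± 0.31), Mmp13 (-3.12 ± 0.07) and Car6 (-3.01 ± 0.34). In WT, Fndc3c1 lay at the background, with 0.51 CPM against 0.58 expected under GM-CSF and 2.36 against 2.28 under EMT6 medium. Its interaction value thus holds a rise of the background. All 19 cholesterol synthesis genes were more positive (median 1.41, adjusted p = 5.71e-40), including Hmgcs1 (2.27 ± 0.07), as were 20 of 23 cell cycle genes (median 1.16, adjusted p = 1.70e-27; 21 up and 0 down adjusted over the list alone) and 8 of 10 primary granule genes (median 1.40, adjusted p = 4.33e-09). ATF4 and amino acid stress genes were more negative in 17 of 19 cases (median -1.18, adjusted p = 4.74e-28), inflammatory genes in 16 of 23 (median -0.68, adjusted p = 5.42e-16), with Cxcl3 (-2.42 ± 0.08) and Il6 (-2.75 ± 0.13). Interferon-stimulated genes were more negative in 12 of 23 (median -0.50, adjusted p = 1.80e-05; 3 up and 15 down adjusted over the list alone). Immediate early and dissociation stress genes were more positive in 11 of 13 cases (median 0.78, adjusted p = 7.01e-13). The interaction was called for 7245 genes, 3746 more positive and 3499 more negative. The more positive share was 51.7% with TMM scaling, 34.0% with DESeq2 size factors, 31.3% with DESeq2, 22.7% without the low-count filter and 35.6% after background subtraction. Of 1798 genes at least 2-fold apart 1369 were more positive. With 1 library left out the share was 34.7% to 49.8%, and without replicate 1 of labelled-deficient GM-CSF 2369 genes were more positive and 4451 more negative.

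**Figure D4:**
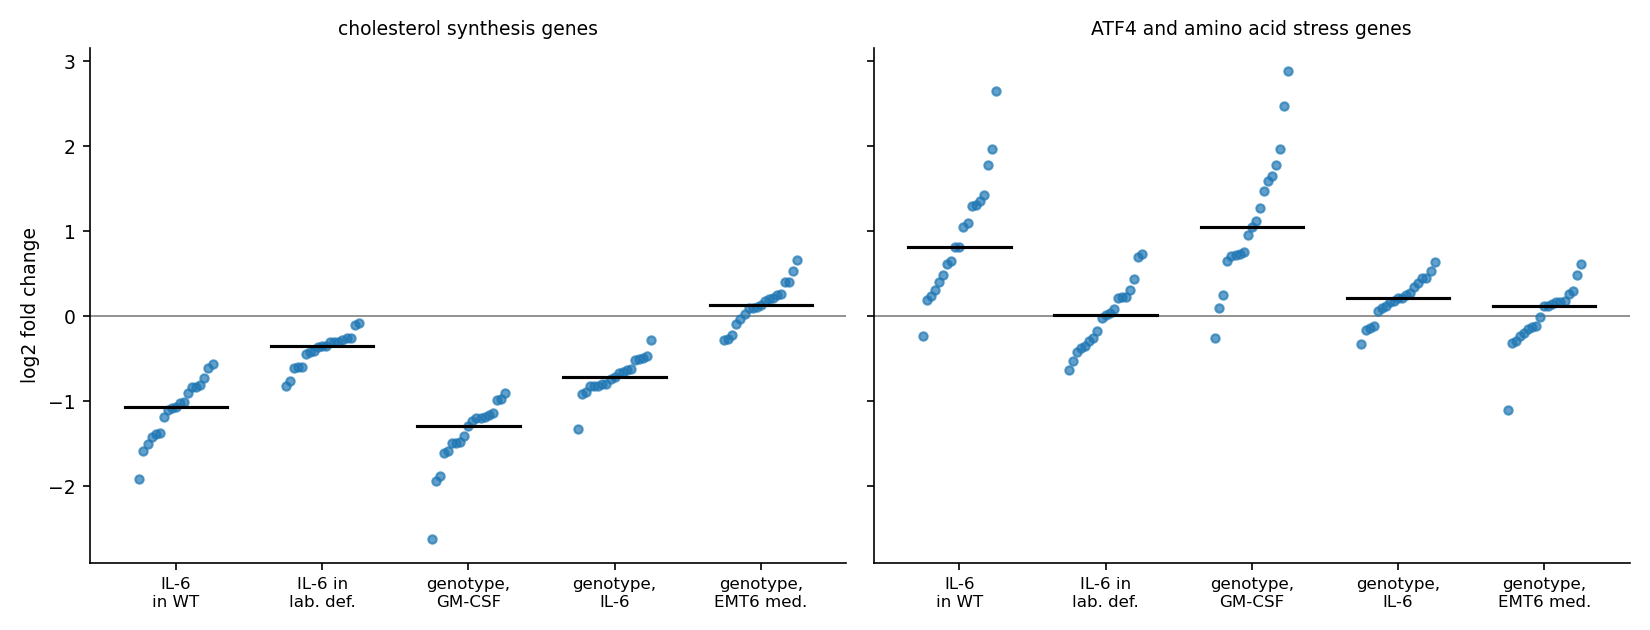
Log2 fold change of each measured cholesterol synthesis gene (19) and ATF4 and amino acid stress gene (19) in 5 comparisons; points are genes and lines are medians. Cholesterol synthesis medians are -1.08, -1.29 and -0.72 under IL-6 in WT and in labelled-deficient cultures with GM-CSF and IL-6, and ATF4 medians are 0.81, 1.05 and 0.21.

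Fold changes were also compared between contrasts that share no library, across genes, which are not independent replicates. The IL-6 effects in WT and labelled-deficient marrow had a Pearson r of 0.175 over 28334 genes and 0.671 over 11175 genes with a mean CPM of at least 5, and 1005 genes were called higher in both, where independent lists would share 163. The EMT6 medium effects of both genotypes had r = 0.891, with 12449 genes higher in both against 7200 for independent lists. Over the 11175 genes with a mean CPM of at least 5, r was 0.892. There 1494 genes were higher in both against 354, and 7304 lower in both against 5753. Most of the 12449 are thus genes of lower abundance, in libraries that share a raised background. The EMT6 medium effect in WT and the IL-6 effect in labelled-deficient marrow had r = 0.260, and the reverse pair r = -0.0135. The genotype effects under GM-CSF and IL-6 had r = 0.466, or 0.799 over genes with a mean CPM of at least 5, with 3555 genes lower in both against 898 for independent lists, or 3281 against 1804 over the latter genes. The genotype effect under EMT6 medium had r = 0.337 with that under GM-CSF and r = 0.458 with that under IL-6, and over genes with a mean CPM of at least 5 these were 0.225 and 0.308. Under GM-CSF and EMT6 medium 2544 genes were lower in both against 965 for independent lists, 933 were higher in both against 922, and 690 and 523 went opposite ways. Under IL-6 and EMT6 medium the counts were 2746 lower against 1032, 1832 higher against 1104, and 402 and 530 opposite. Over genes with a mean CPM of at least 5, 2433 and 2650 were lower in both against 1974 and 2177. Background subtraction brought the r over all genes to 0.203 and 0.288. No p-value is attached to these 7 correlations.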

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

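The tests over all annotated genes, of RNA from EMT6 cells, of swapped labels, of the cholesterol synthesis genes and of the ATF4 and amino acid stress genes, the merging of overlapping genes and the background subtraction for the 37 genes were chosen only after the result was seen.

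The genotypes answered IL-6 differently by an interaction test in 2091 genes and 17 lists (11 lists with an estimated correlation), led by Dynlt1c (1.81), C1qb (1.75) and C1qa (1.65) upward and Soat2 (-2.47), Trib3 (-2.44), Slc6a9 (-2.27) and Slc1a4 (-2.26) downward on the log2 scale. That test uses the WT GM-CSF libraries. A state of those cultures alone stays open for the ATF4 and amino acid stress list, which holds Trib3. The genotypes answered EMT6 medium differently in 7245 genes and 17 lists (10 lists with an estimated correlation), led by Fdps (3.16), Lilra5 (2.99), Retnlg (2.96) and Rtn1 (2.90) and by Fndc3c1 (-4.83), Rbp4 (-3.58), Mmp13 (-3.12) and Car6 (-3.01). Fndc3c1 lay at the background in WT under both GM-CSF and EMT6 medium, which limits its value. Reads outside the tested genes stood above the other cultures in EMT6 medium libraries: in WT 36.2% lay in no annotated feature, 0.208% of feature counts on numbered entries and 0.0844% of gene counts on olfactory and vomeronasal receptor genes, and in labelled-deficient libraries 50.2%, 0.440% and 0.186%.

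Of the 13262 genes called higher with EMT6 medium in WT, 10216 (77.0%) were under 1 CPM in WT GM-CSF cultures. The density of receptor genes, which no carcinoma line transcribes as a family, in WT EMT6 medium libraries was 4.96 times that in WT GM-CSF libraries, which argues against RNA of EMT6 cells as the whole cause. The called genes rose 4.35 times as much per kb as the receptor genes (quartiles 2.22 to 8.73), but genes called for rising are selected upward, so a value above the bound of 2 decides nothing here. Over all annotated genes under 1 CPM the same ratio was 0.732 (quartiles 0.0807 to 2.59), so reads spread evenly over the genome cannot be told apart from transcription, for all of these because the quartiles span the bounds and for the called genes because of that selection. After background subtraction 48.3% of the low-abundance calls remained, between the bounds of 10% and 50%. Reads in no annotated feature, which set that background, had 5.69 counts per kb in WT EMT6 medium libraries. Receptor genes had 2.50 there, so the subtraction may take too much and the share may be too low. This share thus cannot decide, and transcription induced by EMT6 medium stays open for a part of the calls.

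A set of 37 genes changed at least 2-fold the same way in all 3 cultures of libraries labelled deficient (17 higher, 20 lower), and 37.8% of them had another of the set within 1 Mb. Draws of as many genes changed by EMT6 medium in both genotypes gave a median of 5.41% and at most 27.0%, and with overlapping genes merged into 32 loci the value was 28.1%, reached by 1 of 1000 draws, while after background subtraction 33 of the 37 stayed and 42.4% of those had a neighbour (draws at most 24.2%). Neighbours such as Glo1 with Dnah8 and H2-Q5 with H2-Q7 on chromosome 17, Matn4 with Mmp9 on chromosome 2 and Mid1 with 4 overlapping or adjacent genes on the X chromosome make up these clusters, as stretches of DNA from another strain would, and Fndc3c1 of the set lies 89 kb from Cysltr1. In each culture every other split of the 6 libraries called at most 1 gene, against at least 7735 with the labelled genotypes, which argues against genotype labels swapped between some libraries of a culture, while an exchange of both labels as a whole would leave these counts unchanged and stays open. An effect of the receptor itself on these genes, the biological explanation that the design names, was not tested apart from linked DNA and stays open.

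Cholesterol synthesis genes were lower, and ATF4 and amino acid stress genes higher, under IL-6 in WT and in labelled-deficient GM-CSF cultures, and these comparisons share the 3 WT GM-CSF libraries. The genotype effect under IL-6, which does not use those libraries, had 19 of 19 cholesterol synthesis genes lower, which argues against a state of the 3 WT GM-CSF cultures alone. Fewer dividing cells as the whole cause would lower most of them under EMT6 medium too, where 16 of 23 cell cycle genes were lower in labelled-deficient marrow. There 8 cholesterol synthesis genes were higher and 2 lower (4 and 5 without the low-count filter). The cell cycle genes fell less there, with a median of -0.27 against -1.40 under GM-CSF and -0.99 under IL-6. A small fall in division predicts little for the cholesterol synthesis genes, so this comparison cannot decide. For the ATF4 list the larger median among comparisons without a WT GM-CSF library was 0.21 (the other 0.02), between the bounds of 0.1 and 0.41, so a state of those cultures cannot be told apart from joint effects of IL-6 and genotype. An effect of IL-6 and of the receptor on sterol synthesis, which the design names, stays open.

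Other splits of the libraries were tested for chance. For 3 against 3 libraries, 1 of 10 splits, the real one, reached the real count in each comparison, and 10 splits are too few for a share under 0.05. The real counts were 6135 and 23045 for IL-6 and EMT6 medium in WT, 4057 and 24700 in labelled-deficient marrow, 23191 for the direct comparison, and 7735, 8635 and 14749 for the genotype under GM-CSF, IL-6 and EMT6 medium, and the highest other count was 0, or 1 for the genotype under IL-6. Exchanging genotypes within cultures gave a count as large in 1 of 100 splits for the averaged effect (real 15264, highest other 3278), 3 of 100 for the interaction with IL-6 (2091, highest other 5248) and 2 of 100 for that with EMT6 medium (7245, highest other 10786). Groups that mix genotypes hold the genotype effect as spread between replicates, so many of these splits called 0 genes. They would do so with or without an interaction. The shares for the interactions thus cannot decide about chance. The split with 10786 gives all 6 GM-CSF libraries the other genotype and leaves the EMT6 medium libraries theirs, so its interaction adds genotype effects of the cultures instead of taking their difference, which is a structure of the samples. The same split holds the 5248, although it also gives 2 of the IL-6 libraries the other genotype. Another split called 2130 genes for the interaction with IL-6. It exchanges all 6 GM-CSF libraries, 2 IL-6 libraries and 4 EMT6 medium libraries.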

How the results depend on the processing

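Background subtraction, leaving out the EMT6 medium libraries and the location of genes changed at least 2-fold were chosen only after the result was seen.

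The total counts of called genes stayed within 1.5 times of their values under DESeq2, DESeq2 size factors, no low-count filter, only the groups compared, background subtraction and each library left out. With 1 library left out they ranged from 5073 to 6013 for IL-6 in WT, 22036 to 22560 for EMT6 medium in WT, 3096 to 3403 for IL-6 and 24127 to 24728 for EMT6 medium in labelled-deficient marrow, 22354 to 22760 for the direct comparison, 6576 to 7838, 6792 to 8182 and 11826 to 14129 for the genotype under GM-CSF, IL-6 and EMT6 medium, 14201 to 15683 averaged, and 1489 to 2240 and 6472 to 7419 for the interactions with IL-6 and EMT6 medium. The balance of higher and lower calls was less stable, and its cause was not tested. With 1 library left out the higher share ran from 45.9% to 59.9% for the genotype under EMT6 medium, 46.0% to 54.9% averaged, 34.7% to 49.8% for the interaction with EMT6 medium and 44.3% to 50.5% for IL-6 in WT, against 62.0%, 54.4%, 51.7% and 47.9% with all libraries. Fewer tested genes lowered the counts with the filter at mean CPM of 5 to 12611 for EMT6 medium in WT, 12914 in labelled-deficient marrow, 12556 against IL-6 and 9461 for the genotype under EMT6 medium. Requiring an absolute log2 fold change of at least 1 left 574 and 15319 genes for IL-6 and EMT6 medium in WT, 332 for IL-6 in labelled-deficient marrow, 1210, 1559 and 3936 for the genotype by culture, 1395 averaged, and 185 and 1798 for the interactions, and 18055 for EMT6 medium in labelled-deficient marrow and 15707 against IL-6, which lie within 1.5 times. That threshold is stricter by construction.

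The replicate block, with the replicate number as a term, gave 6174, 23027, 4114, 24668, 23172, 7768, 8638, 14716, 15248, 2151 and 7253 genes in the order above. Deviations of libraries with the same number correlated over 0.1 throughout in 0 of 15 pairs of groups (r from -0.302 to 0.356), and the best match was the own number in 15 of 45 cases. The numbers thus showed no pairing across all groups. The own number matched best each time for WT GM-CSF with WT IL-6 (r = 0.0365, 0.171 and 0.356). It also did for labelled-deficient IL-6 with EMT6 medium, so pairing of some cultures cannot be excluded.

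Of 188 list calls, 115 stayed with an estimated correlation, 184 with fry, 188 with the replicate block and 171 after background subtraction, and 0 turned direction. Why the estimated correlation ends calls was not tested. Of 2472 values of named genes under other settings, 2427 kept direction and side of the threshold, 45 lost the call and 0 reversed. With 1 library left out 1942 of 1944 kept them.

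Agreement depended on the genes and the measure, and the cause was not tested. Spearman rho was 0.201 for IL-6 in both genotypes, 0.885 for EMT6 medium in both, 0.290 for EMT6 medium in WT with IL-6 in labelled-deficient marrow, 0.508 for the genotype under GM-CSF and IL-6 and 0.505 under IL-6 and EMT6 medium. Over genes with a mean CPM of at least 5, r was 0.671 for IL-6 in both genotypes, 0.360 for EMT6 medium in WT with IL-6 in labelled-deficient marrow, and 0.799, 0.225 and 0.308 for the genotype under GM-CSF and IL-6, GM-CSF and EMT6 medium, and IL-6 and EMT6 medium. After background subtraction it was 0.839 for EMT6 medium in both genotypes, 0.183 for EMT6 medium in WT with IL-6 in labelled-deficient marrow, and 0.434, 0.203 and 0.288 for those 3 pairs.

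The X chromosome odds ratio of 0.865 reversed to 1.48 (Fisher's exact test p = 0.00297) among genes changed at least 2-fold and was 0.872 (p = 0.0692) after background subtraction. Near Cysltr1 it was 0.999 (Fisher's exact test p = 1) in a 20 Mb window without Cysltr1 and 2.23 (p = 0.00351) among genes changed at least 2-fold. All of the latter genes but Fndc3c1 lay under a mean CPM of 5 in every group. With the filter at mean CPM of 5 the odds ratio was 1.72 within 10 Mb of Cysltr1 (Fisher's exact test p = 0.0839). On the X chromosome it was 0.806 with that filter (Fisher's exact test p = 0.0471). The cause was not tested.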

Other observations

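No test in this part was chosen only after the result was seen.

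Markers of other lineages also moved. In labelled-deficient marrow with IL-6, against WT, erythroid and megakaryocyte genes were higher in 9 of 12 cases and lower in 1 (median 0.59, adjusted p = 6.18e-05), including carbonic anhydrase Car2 (1.03 ± 0.07), the platelet integrin Itga2b (0.43 ± 0.05), the globin Hbb-bs (2.90 ± 0.35) and the transcription factor Gata1 (0.47 ± 0.08). Eosinophil genes were lower in 7 of 10 cases (median -1.31, adjusted p = 3.95e-06), including the granule proteins Epx (-1.95 ± 0.06) and Prg2 (-1.91 ± 0.06). Immediate early and dissociation stress genes were lower in 8 and higher in 3 of 13 cases (median -0.45, adjusted p = 3.91e-06, and adjusted p = 0.0624 with an estimated correlation). IL-6 itself raised 6 of 13 mast cell and basophil genes in labelled-deficient marrow (median 0.23, adjusted p = 4.18e-05), with the stem cell factor receptor Kit (0.88 ± 0.08), the protease Cpa3 (0.47 ± 0.07) and the basophil protease Mcpt8 (0.40 ± 0.09), and 4 of 12 erythroid and megakaryocyte genes (median 0.34, adjusted p = 2.87e-06; 5 up and 0 down adjusted over the list alone), with the platelet chemokine Pf4 (1.01 ± 0.06). The interaction with genotype was more positive for 6 of the 13 mast cell and basophil genes (median 0.36, adjusted p = 1.92e-05), with Kit at 0.76 ± 0.11.

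Under GM-CSF alone, labelled-deficient cultures had lower lymphoid genes in 10 of 16 cases and higher in 1 (median -0.44, adjusted p = 0.000115), with Nkg7 (-2.62 ± 0.14), the immunoglobulin gene Ighm (-0.94 ± 0.05) and the B cell receptor gene Cd79a (-0.80 ± 0.08). Immediate early and dissociation stress genes were lower in 12 of 13 cases (median -0.72, adjusted p = 7.13e-13), including the RNA-binding regulator Zfp36 (-1.12 ± 0.06) and Btg2 (-0.72 ± 0.05). Progenitor genes had no common direction, with 3 higher and 6 lower of 12 (median -0.14, adjusted p = 0.216; 4 up and 6 down adjusted over the list alone), for example Myb (-0.88 ± 0.06) and Gfi1 (-0.92 ± 0.07) lower and Sox4 (0.80 ± 0.08) higher. EMT6 medium in WT marrow lowered the progenitor genes Cd34 (-2.45 ± 0.06), Cebpa (-2.0 ± 0.05) and Cdk6 (-1.65 ± 0.06) and raised Ly6a, an interferon-responsive surface marker (4.90 ± 0.17), with 6 of 12 up and 6 down (median 0.04, adjusted p = 0.414).

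Some values belong to no comparison. Numbered entries, whose names the files do not resolve, took 0.0473%, 0.0471% and 0.208% of feature counts in WT GM-CSF, IL-6 and EMT6 medium libraries and 0.0631%, 0.0735% and 0.440% in labelled-deficient ones. The number of genes with any count averaged 34618, 34718 and 38553 in WT and 35589, 36435 and 39015 in labelled-deficient libraries, highest in EMT6 medium libraries despite their lower depth.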
